A study of Mus musculus with 24 samples.

How the data were processed

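RNA of primary alveolar macrophages from wild-type BALB/cJ mice, the resident phagocytes of the air spaces, was sequenced 20 h after stimulation. The cells were left untreated or received recombinant IL-13, IL-33 or IL-17A, singly and in every combination, which gave 8 groups of 3 libraries. Total RNA was taken with a column kit for small samples and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Groups were taken from the treatment label of each sample. Replicate numbers within a group only name the libraries, because the labels give none that run across groups. No label says that the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

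Each library had 1 deposited table of 17017 genes with Ensembl identifiers, symbols, coordinates, a gene length and a TPM value. Reads were aligned with STAR to mm10, per the submitters' processing notes, and the version, the counting tool and the handling of strand are not given in the sources used here. The TPM values sum to the same total in each library, and per the file headers the length behind them is a column of its own. For all 17017 genes that length equalled the gene's span, introns included, with a median of 9.7 times the mean transcript length in the GENCODE M21 annotation of GRCm38. A gene with long introns therefore has a low value whatever its expression, so levels below compare libraries for 1 gene and not genes with each other. Of the identifiers, 16998 were in GENCODE M21, 16907 with the same start and 16895 with the same end once 1 base was subtracted from the deposited stop. Coordinates are given 1-based on mm10, as in the deposited tables with that base removed.

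TPM keeps no depth of its own, but TPM multiplied by the gene span was a whole multiple of 1 constant per library for 89.9% to 91.4% of values of up to 20 reads, within 0.05 reads, where 10.0% would be whole by chance. With transcript lengths the share was 25.0% to 29.3%. Reads recovered in this way came to 9.13 to 12.89 M per library, with a median of 10.6 M, and 1 TPM of a gene spanning 10000 bases stood for 8.8 to 13.0 reads. The tested genes had a median of 269 reads. Mitochondrial genes took 0.77% to 1.08% of recovered reads and the 10 most abundant genes 5.7% to 6.6%. All 24 pairs of libraries within groups differed by more than sampling noise, with an index of dispersion of 1.43 to 21.74 over genes with at least 20 reads in the pair. This spread may be technical and cannot tell whether libraries came from separate cultures. Each library was counted as 1 replicate.

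The design fixed before the data were examined had foreseen read counts. As the deposited tables held TPM, the test written for that case was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with genes at 1 TPM or more in at least 3 libraries (13215 genes), 8 group means in 1 fit of all 24 libraries, no covariates and 16 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 13215 genes of 1 comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near 1 TPM. The 15 comparisons fixed before the data were examined were each of the 7 stimulated groups against untreated cells, 5 comparisons that add 1 cytokine to another stimulation, and the 3 pairwise interactions in the absence of the remaining cytokine. The standard error of a log2 fold change had a median of 0.102, and of 0.074 for genes with a mean of 10 TPM or more.

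Genes are named by a rule that was also fixed before the data were examined. Against untreated cells it takes the 8 largest log2 fold changes in each direction, and elsewhere the 5 largest, among called genes with a group mean of at least 5 TPM, all 3 libraries of 1 group beyond all 3 of the other and a symbol that is not a provisional one. It adds up to 4 called members of each gene list with the smallest p (up to 2 where none was called), the cytokine receptors, and a set of type 2 and inflammatory markers with the cytokines themselves. The minimum of 5 was written for CPM and applied to TPM.

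There were 20 gene lists, fixed at the same time: alternative activation, inflammatory NF-kB targets, IL-17A targets of stromal and epithelial cells, cytokine receptors, alveolar macrophage identity, monocyte and interstitial macrophage genes, cell cycle, cholesterol biosynthesis, lipid handling, interferon response, antigen presentation and costimulation, matrix and tissue remodelling, hypoxia and glycolysis, integrated stress response, and markers of fibroblasts, epithelium, endothelium, lymphocytes, granulocytes and mast cells, and dendritic cells. The 15 lists with at least 3 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of 1 comparison, with the same test at an estimated correlation beside it. Counts of called members are given over all genes and adjusted over the list alone. They cover tested members only, such as 21 of 26 genes of alternative activation, 26 of 31 of the cell cycle and 8 of 18 IL-17A targets. A low gene could pass the filter through stimulated groups alone, which favours rises among low members. The lists share some members, such as Cxcl1, Nfkbiz, Saa3 and Zc3h12a in both the NF-kB and the IL-17A lists.

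The fit was tested on simulated data made from these libraries, with 200 genes changed by known folds. For IL-33 against untreated (12920 genes), 100% of 2-fold changes, 86.2% of 1.5-fold and 62.5% of 1.25-fold changes were recovered at 10 TPM or more, and 66.7% of 2-fold changes at 1 to 10 TPM. Of 148 genes called there, 6 had not been changed. For the interaction of IL-33 and IL-13 (12910 genes), 87.5% of 2-fold and 79.4% of 1.5-fold changes were recovered at 10 TPM or more and 38.9% of 2-fold changes at 1 to 10 TPM. Of 131 genes called there, 10 had not been changed. The simulated libraries were less noisy than the real ones (median SE 0.078 against 0.102, and 0.111 against 0.145 for the interaction), so these shares are optimistic.

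Alternatives tried were a pseudocount of 0.1, no filter on low values, only the libraries of the groups compared, the 4 libraries numbered above 24 in their titles left out or marked by a covariate, and each library left out in turn. The libraries numbered above 24 were all in groups with IL-33. They were number 30 (IL-33 replicate 3), 31 and 32 (IL-33+IL-17A replicates 2 and 3) and 36 (triple combination replicate 3). Leaving them out left IL-33+IL-17A with replicate 1 only. Added after the data were seen were median-ratio scaling, voom in limma on the recovered reads with the same genes or with at least 10 reads in 3 or more libraries, a covariate for each library's slope on transcript length, and the 3 libraries standing apart on the second principal component left out. Also added then were 6 comparisons: the triple combination against IL-13+IL-17A, the interaction of IL-33 and IL-13 with IL-17A present, IL-13+IL-17A against IL-17A, and the averages of IL-17A over 4 backgrounds and of IL-33 over the 2 backgrounds without and the 2 with IL-13. Tests on count models other than voom were not run, since the deposited unit is TPM. Principal components were taken from log2(TPM + 1) of the tested genes, and the other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.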

Results

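Alveolar macrophages live on the surface of the air spaces, and IL-13, IL-33 and IL-17A are cytokines of allergic and neutrophilic lung inflammation. The series title concerns lung fibroblasts that answer to these 3 cytokines and secrete factors that activate macrophages, and the libraries described here are of the macrophages themselves, given the cytokines directly. The 24 libraries held 9.13 to 12.89 M recovered reads each, and 11569 to 12204 genes at 1 TPM or more. Mean depth per group ran from 9.98 ± 0.831 M reads with IL-33 (SD, n = 3) to 12.1 ± 0.888 M with IL-17A. Libraries were alike within groups (Pearson r across genes 0.974 to 0.985) and nearly as alike between groups (0.961 to 0.985). The first principal component held 26.4% of the variance and parted the 12 libraries with IL-13 from the 12 without. The second held 8.9% and set apart untreated replicate 1, IL-17A replicate 2 and, farthest out, replicate 2 of the triple combination.

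**Figure D1:**
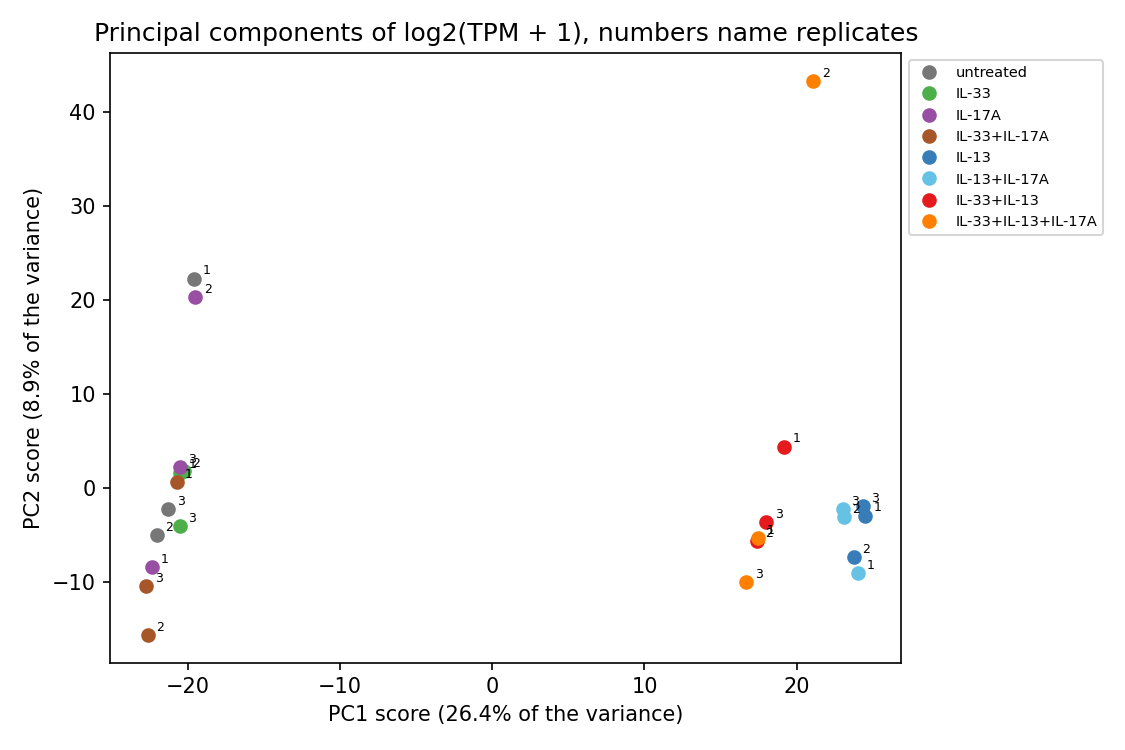
Scores of the 24 libraries on the first (x axis, 26.4% of the variance) and second (y axis, 8.9%) principal components of log2(TPM + 1), coloured by group, with replicate numbers beside the points. Libraries with and without IL-13 separate along the x axis, and replicate 2 of the triple combination has the highest score on the y axis, at 43.3.

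The first question was what IL-13, the cytokine that drives alternative activation of macrophages, did on its own. Cish, a feedback inhibitor of STAT signalling, went from 0.934 ± 0.727 TPM in untreated cells to 135 ± 13.1 TPM with IL-13 (SD, n = 3 per group). Ocstamp, a membrane protein needed for macrophage fusion, went from 0.0506 ± 0.0876 to 35.98 ± 0.644 TPM, and Ch25h, which makes 25-hydroxycholesterol, from 43.3 ± 8.11 to 952.5 ± 22.3 TPM. The chemokine genes Cxcl3, whose product draws neutrophils, and Ccl22, whose product draws lymphocytes, rose from 5.83 ± 1.46 to 147 ± 11.9 TPM and from 0.817 ± 0.562 to 23.6 ± 2.49 TPM. Hp, which encodes the haemoglobin scavenger haptoglobin, fell from 93.55 ± 7.65 to 14.1 ± 1.22 TPM, and Lyl1, a transcription factor of blood cells, fell from 44.6 ± 4.1 to 6.38 ± 0.247 TPM.

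On the log2(TPM + 1) scale the 8 largest increases were Cish by 6.20 (limma, SE 0.2, adjusted p = 2.32e-14), Rnase2a by 5.33 (adjusted p = 4.84e-11), Ocstamp by 5.14 (adjusted p = 3.2e-19), Cxcl3 by 4.46 (adjusted p = 4.5e-12), Ch25h by 4.44 (adjusted p = 1.15e-15), the collagenase gene Mmp13 by 4.39 (adjusted p = 9.22e-15), the claudin gene Cldn23 by 3.885 and Ccl22 by 3.80. Rnase2a belongs to a family of near-identical ribonuclease genes, so its reads could have been shared with other members and its value is uncertain. The largest decreases were Lrrc14b (-2.98, limma adjusted p = 4.26e-06), Hp (-2.65), Lyl1 (-2.625), Cdo1 (-2.425), Cdkn1c (-2.30), Gpr132 (-2.08), the ribosomal pseudogene Rpl19-ps7 (-2.06, adjusted p = 0.00461) and Cxcr2 (-2.04). Cdo1 encodes cysteine dioxygenase, Cdkn1c the cell cycle inhibitor p57, Gpr132 a lipid-sensing receptor, and Cxcr2 the receptor of chemokines such as that of Cxcl3. Rpl19-ps7 is uncertain because it could take reads of its parent gene, and Lrrc14b because it overlaps Ccdc127 on the other strand. Cish (ENSMUSG00000032578) lies on mm10 chromosome 9, bases 107296026 to 107302784. Cxcl3 (ENSMUSG00000029379) lies on chromosome 5, bases 90786103 to 90789600. Ch25h (ENSMUSG00000050370) lies on chromosome 19, bases 34473778 to 34475164. Ocstamp (ENSMUSG00000027670) lies on chromosome 2, bases 165393760 to 165400405. Hp (ENSMUSG00000031722) lies on chromosome 8, bases 109575128 to 109579172. These values are sums over each whole gene, and all 5 are protein-coding. In total 3932 of 13215 genes passed the threshold with IL-13, 1857 higher and 2075 lower, of which 230 and 138 changed by at least 2-fold on that scale. With median-ratio scaling 2239 were higher and 2003 lower, so which direction held more genes rested on the scaling.

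Of 21 tested genes of alternative activation, 19 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 2.79e-24, and adjusted p = 0.000204 with an estimated correlation). Mgl2, Clec10a, Pdcd1lg2, Alox15 and Itgb3 of the 26 listed genes were not tested. Some members, such as Arg1, Ccl17 and Ccl24, passed the filter only through groups with IL-13, which favours rises in this count. Chil3, which encodes the chitinase-like protein Ym1, rose from 382 ± 2.9 to 5170 ± 130 TPM, Irf4, a transcription factor of the IL-4 and IL-13 response, from 2.52 ± 0.26 to 39.1 ± 1.9 TPM. Cdh1, encoding E-cadherin, rose from 3.54 ± 0.34 to 38.1 ± 1.0 TPM, and Tgm2, encoding transglutaminase 2, from 121 ± 9.1 to 446 ± 10 TPM. Chil3 and Chil4 are near-identical copies, so the division of reads between them is uncertain. The classical marker Arg1, arginase 1, was at 0.056 ± 0.048 and 1.41 ± 0.27 TPM (adjusted p = 2.8e-06). Ccl17 and Ccl24 were listed at 0 in every untreated library and had means of 2.70 ± 2.1 and 1.012 ± 0.456 TPM with IL-13. Matk (32.98 ± 0.844 and 35.3 ± 1.3 TPM) and Retnla (0 and 0.311 ± 0.54 TPM), which encodes the type 2 marker RELM-alpha, did not pass.

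Of 26 tested cell cycle genes, 24 rose with IL-13 and none fell (25 adjusted over the list alone, camera adjusted p = 4.08e-15, and adjusted p = 0.00381 with an estimated correlation). The proliferation marker Mki67 rose from 1.40 ± 0.34 to 6.53 ± 0.32 TPM, and the replication genes Rrm2, a ribonucleotide reductase subunit, and Mcm5, a replicative helicase subunit, from 3.66 ± 0.61 to 14.02 ± 1.15 TPM and from 6.63 ± 0.92 to 19.1 ± 1.9 TPM. Pcna stood at 500 ± 12 and 503 ± 15 TPM. Of 16 integrated stress response genes, 11 rose and none fell (14 adjusted over the list alone, camera adjusted p = 4.68e-09, and adjusted p = 0.00685 with an estimated correlation). They included the serine synthesis genes Psat1, from 9.84 ± 0.099 to 23.2 ± 1.0 TPM, and Phgdh, from 42.6 ± 3.4 to 81.5 ± 1.7 TPM. The mitochondrial folate enzyme gene Mthfd2 rose from 25.3 ± 1.0 to 46.4 ± 1.3 TPM.

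Other lists were mixed or lost their call when the correlation was estimated. Of 21 cholesterol synthesis genes 14 rose and none fell (15 adjusted over the list alone, camera adjusted p = 1.56e-08, but adjusted p = 0.144 with an estimated correlation), with Fdps from 217 ± 1.6 to 345 ± 13 TPM and Mvd from 109 ± 4.9 to 155 ± 4.1 TPM. Of 18 genes of hypoxia and glycolysis 11 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.000628, but adjusted p = 0.201 with an estimated correlation). Lactate dehydrogenase Ldha rose from 418 ± 4.7 to 810 ± 12 TPM, while the lactate exporter gene Slc16a3 fell from 163 ± 3.4 to 126 ± 4.3 TPM. Of 21 NF-kB targets 12 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.00211, but adjusted p = 0.246 with an estimated correlation). Il1b rose from 5.34 ± 0.66 to 66.01 ± 6.4 TPM, Cxcl2 from 33.4 ± 7.7 to 76.5 ± 6.4 TPM and Cxcl1 from 14.9 ± 3.3 to 33.2 ± 6.3 TPM. Nfkbiz fell from 2.80 ± 0.28 to 1.11 ± 0.32 TPM, and Tnf was at 127 ± 9.1 and 123 ± 8.5 TPM. Of 21 alveolar macrophage identity genes 12 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.0063, but adjusted p = 0.112 with an estimated correlation). The nuclear receptor gene Pparg rose from 8.23 ± 0.30 to 22.6 ± 0.86 TPM and the ribonuclease gene Ear2, whose near-identical relatives make it uncertain, from 687 ± 91 to 4190 ± 410 TPM. The sialic acid receptor gene Siglecf fell from 531 ± 4.0 to 303 ± 13 TPM.

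The remaining lists gave no call as groups, though single members moved. Of 16 matrix and remodelling genes 8 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.396). The metalloproteinase gene Mmp19 rose from 64.9 ± 2.5 to 473 ± 7.6 TPM, the growth factor gene Igf1 from 6.11 ± 0.086 to 20.7 ± 1.4 TPM, and osteopontin, Spp1, fell from 763 ± 9.7 to 352 ± 17 TPM. Of 20 lipid handling genes 7 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.422). The scavenger receptor gene Cd36 rose from 152 ± 5.4 to 274 ± 3.3 TPM and apolipoprotein E, Apoe, fell from 243 ± 27 to 84.9 ± 10 TPM. Of 12 monocyte and interstitial macrophage genes 3 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.872), with the endotoxin co-receptor gene Cd14 falling from 1520 ± 28 to 651 ± 34 TPM. Of 8 antigen presentation genes 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.641). Of 15 interferon response genes 1 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.743). Of 8 IL-17A targets of stromal cells 4 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.459).

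Among receptors, Il17ra, a subunit of the IL-17A receptor, fell with IL-13 from 47.6 ± 2.9 to 29.1 ± 1.6 TPM (limma adjusted p = 1.5e-05). Il4ra, a subunit of the IL-13 receptor, fell from 9.65 ± 1.0 to 7.47 ± 0.30 TPM, and Il1rap, the shared subunit of the IL-33 receptor, rose from 1.52 ± 0.15 to 2.59 ± 0.12 TPM. These were the called members among 5 tested (1 up and 2 down, the same adjusted over the list alone, camera adjusted p = 0.422), and Il13ra1 (13.6 ± 1.3 and 12.5 ± 0.74 TPM) and Il2rg (420 ± 4.0 and 392 ± 8.7 TPM) were not called. The IL-33 receptor gene Il1rl1, on chromosome 1, bases 40429570 to 40465415, reached a group mean of at most 0.136 TPM, with 57 estimated reads over all 24 libraries. That mean was with IL-13 (SD 0.1). Il1rl1 was at 0.132 ± 0.029 TPM with IL-13+IL-17A, 0.0934 ± 0.026 in the triple combination and 0.0388 ± 0.019 with IL-33+IL-13. Groups without IL-13 had 0.0188 to 0.0484 TPM, and differences at so few reads were not tested. Il17rc, the other subunit of the IL-17A receptor, on chromosome 6, bases 113471427 to 113483140, reached at most 0.724 TPM with 146 estimated reads. Neither entered the tests. Il33 reached at most 0.0304 TPM as a group mean, with IL-33+IL-17A, and Il13ra2, Il17rd, Il6, Il13 and Il17a were not analysed here.

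Markers of other cell types were listed in untreated cells, and their sums depend on gene spans, so they do not measure the share of those cells. The fibroblast genes summed to 5.82 TPM, the epithelial ones to 20.3, the endothelial ones to 10.7, the dendritic cell ones to 3.78 and those of granulocytes and mast cells to 15.9 TPM. The lymphocyte list summed to 182 TPM, nearly all of it Il7r, at 181 TPM. Single genes also made up most of the other sums: Pdgfra (5.24 TPM), Hopx (11.9), Vwf (10.1), Clec9a (3.25) and Cxcr2 (9.2), in the order given. Few markers were tested: 1 of 14 for fibroblasts, 5 of 14 for epithelium and 1 of 10 for endothelium. For lymphocytes it was 2 of 16, for granulocytes and mast cells 2 of 17 and for dendritic cells 1 of 8. Col1a1, Dcn and Sftpc were among those not tested. With IL-13 several of the tested markers were lower, which does not show that such cells were present. The fibroblast gene Pdgfra went from 5.24 ± 0.94 to 2.32 ± 0.33 TPM (limma adjusted p = 4.7e-05). Of the 5 tested epithelial genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0506), among them Hopx and Epcam. The granulocyte receptor gene Csf3r fell from 6.38 to 1.52 TPM beside Cxcr2. The endothelial gene Vwf (10.1 and 9.37 TPM), Il7r and the dendritic cell gene Clec9a (3.25 and 3.29 TPM) were not called.

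**Figure D2:**
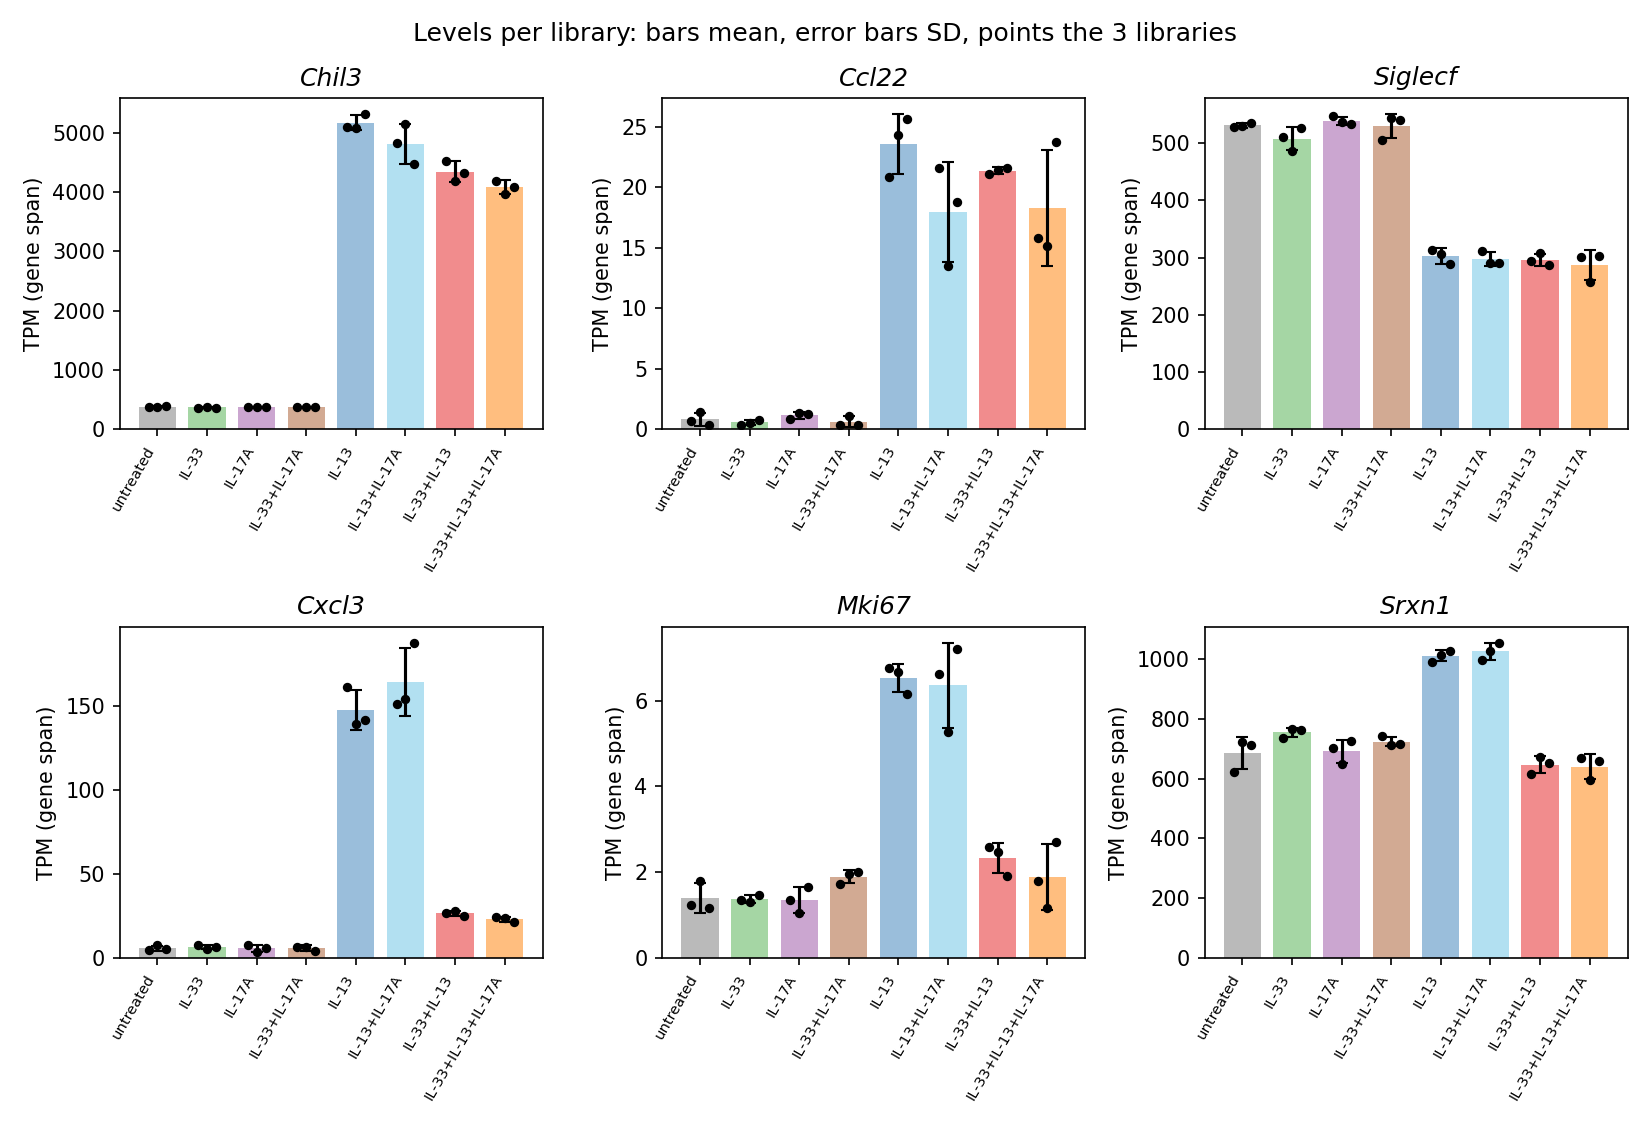
Levels of 6 genes in TPM on the gene span (y axes, linear from 0) in the 8 groups (x axes), with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. Chil3 is near 382 TPM without IL-13 and at 5170 TPM with it, whereas Cxcl3 is at 147 TPM with IL-13 and 26.5 TPM with IL-33+IL-13.

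IL-33 is an alarmin released by damaged lung tissue, and IL-17A a cytokine of neutrophilic inflammation, and the next question was what each did without IL-13. With IL-33 alone no gene passed the threshold, and Chil3 was at 366 ± 4.8 TPM beside 382 ± 2.9 TPM in untreated cells. The inflammatory cytokine genes Tnf (127 ± 9.1 TPM untreated, 160.1 ± 17 with IL-33) and Il1b (5.34 ± 0.661 and 7.15 ± 1.12 TPM) had the smallest p of the NF-kB list, with limma adjusted p = 0.785 and 1. limma called 0 of 13215 genes, with 484 at an unadjusted p under 0.05 and a smallest adjusted p of 0.69, and voom on recovered reads called 0 as well. Of the NF-kB targets 1 was called, as higher, adjusted over the list alone, and the list was higher by camera (adjusted p = 6.84e-05), but with adjusted p = 0.336 with an estimated correlation. Hypoxia and glycolysis genes were called higher and lipid handling genes lower by camera (adjusted p = 0.0166 each), both with adjusted p = 0.561 with an estimated correlation, and no member of either was called.

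With IL-17A alone Cxcl1, a known IL-17A target in stromal cells, was at 14.2 ± 3.1 TPM beside 14.9 ± 3.27 TPM in untreated cells, and Mmp13 at 18.2 ± 1.66 beside 23.3 ± 4.69 TPM. limma called 0 genes (469 at an unadjusted p under 0.05, smallest adjusted p 0.32), as did voom on recovered reads. None of the 8 tested IL-17A targets was called over all genes or adjusted over the list alone (camera adjusted p = 0.476). The list held 18 genes, and Lcn2, Cxcl5, Csf3, Il6, Ccl20, Mmp3, Steap4 and S100a9 were among those not tested. Most of the list was therefore not assessed. Camera called the integrated stress response list higher and lipid handling lower (adjusted p = 0.031 each), but with adjusted p = 0.614 and 0.803 with an estimated correlation. In these lists 1 stress response gene was called adjusted over the list alone, as were 1 of alternative activation and 1 of monocytes and interstitial macrophages.

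With IL-33 and IL-17A together Il1b was at 4.45 ± 0.285 TPM beside 5.34 ± 0.661 TPM untreated, Tnf at 121 ± 10.7 beside 127 ± 9.1 TPM, and Chil3 at 370 ± 1.46 beside 382 ± 2.9 TPM. limma called 0 genes (501 at an unadjusted p under 0.05, smallest adjusted p 0.68), as did voom on recovered reads, and no list was called by camera (1 matrix gene was higher adjusted over the list alone). For genes at 10 TPM or more, the 95% interval of the fold change excluded a 2-fold change for 98.1% of 6813 genes with IL-33 and 98.0% with IL-17A. For the 6402 genes below 10 TPM these shares were 73.6% and 73.8%. The intervals are on the log2(TPM + 1) scale, which understates the change of low genes. A 2-fold change in TPM was therefore not excluded below 10 TPM. Fitted on the groups compared alone, limma called 2 genes with IL-33 (Gm17194 and Gm2225), 5 with IL-17A (Cox6c2, Gm16089, Rpl13-ps5, Gm7774 and Rpl31-ps12) and 3 with both (Gm5239, Gm4853 and Gm43148). All but Gm43148 are annotated as processed pseudogenes and are uncertain.

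IL-13 together with IL-17A gave levels close to those of IL-13 alone. Cish was at 136 ± 9.04 TPM (135 ± 13.1 with IL-13), Cxcl3 at 164 ± 20.2 TPM (147 ± 11.9), Mmp13 at 531 ± 42.9 TPM (502 ± 0.59) and Hp at 14.3 ± 1.16 TPM (14.1 ± 1.22). Against untreated cells the largest log2 increases were Cish (6.21), Rnase2a (5.20), Ocstamp (4.955), Cxcl3 (4.61), Mmp13 (4.47), Ch25h (4.38), Cldn23 (3.65) and Chil3 (3.65). The largest decreases were Lrrc14b (-2.88), Lyl1 (-2.65), Hp (-2.63), Cxcr2 (-2.17), Cdkn1c (-2.15), the troponin gene Tnni2 (-2.09), Cdo1 (-2.06) and Gpr132 (-2.02). In all limma called 3900 genes, 1849 higher and 2051 lower, or 2155 and 2073 with median-ratio scaling. Alternative activation genes (19 of 21 up), cell cycle genes (25 of 26 up) and integrated stress response genes (12 of 16 up) were called as groups, with camera adjusted p = 0.000295, 0.00303 and 0.0064 with an estimated correlation. Adjusted over the list alone the counts were 19, 25 and 14.

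Set directly against IL-13, the addition of IL-17A gave no call. The NF-kB genes Tnf (123 ± 8.52 TPM with IL-13, 140 ± 8.95 with both), Ccl3 (94.75 ± 3.08 and 113 ± 11.6 TPM) and Cxcl2 (76.5 ± 6.38 and 93.4 ± 4.72 TPM) had limma adjusted p = 1. limma called 0 genes (373 at an unadjusted p under 0.05), as did voom on recovered reads. Camera called NF-kB targets higher (adjusted p = 0.000662) and alternative activation lower (adjusted p = 0.018), both with adjusted p = 0.346 with an estimated correlation and with no member called over all genes or adjusted over the list alone. The interaction of IL-13 and IL-17A gave 0 genes by limma (372 at an unadjusted p under 0.05, smallest adjusted p 0.25), with Mmp13 at 0.40 (log2, SE 0.188). Its terms for alternative activation (negative), NF-kB targets (positive) and IL-17A targets (positive) had camera adjusted p = 0.0295 each, but adjusted p = 0.609, 0.609 and 0.148 with an estimated correlation.

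The combination of IL-33 and IL-13 was set against untreated cells and against IL-33. Against untreated cells Cish was at 126 ± 8.65 TPM, Ccl22 at 21.4 ± 0.278 TPM and Chil3 at 4340 ± 171 TPM, while Cxcl16, a transmembrane chemokine gene, fell from 231 ± 11.6 to 65.1 ± 0.991 TPM and Hp from 93.55 ± 7.65 to 12.5 ± 1.01 TPM. The largest log2 increases were Cish (6.10), Rnase2a (5.24), Ocstamp (4.64), Ch25h (3.93), Ccl22 (3.67), Chil3 (3.5), Irf4 (3.43) and Mmp13 (3.40). The largest decreases were Hp (-2.81), Lrrc14b (-2.80), Cdo1 (-2.16), Lyl1 (-2.05), Cxcl16 (-1.81), Pilrb2 (-1.80), Zmynd15 (-1.79) and Sema4d (-1.74). Zmynd15 overlaps Cxcl16 on the other strand and Pilrb2 has a close paralog, so both are uncertain. limma called 3310 genes, 1466 higher and 1844 lower, or 1861 higher and 1739 lower with median-ratio scaling. Alternative activation (19 of 21 up) and the integrated stress response (13 of 16 up) were called by camera with adjusted p = 0.000102 and 0.00296 with an estimated correlation, with 19 and 14 adjusted over the list alone. For the cell cycle list 13 of 26 were up (13 adjusted over the list alone, camera adjusted p = 5.6e-06, but adjusted p = 0.0614 with an estimated correlation). Epithelial markers were lower (4 of 5 down, 4 adjusted over the list alone, camera adjusted p = 0.0235, but 0.0614 with an estimated correlation).

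Against IL-33, a comparison with its own control libraries, adding IL-13 raised Cish (log2 6.06), Rnase2a (5.98), Ocstamp (4.71), Ccl22 (3.86) and Ch25h (3.73), and lowered Hp (-3.13, from 117.5 ± 9.94 to 12.5 ± 1.01 TPM), Lrrc14b (-2.12), Pilrb2 (-1.96), Zmynd15 (-1.95) and Lyl1 (-1.86). limma called 3161 genes, 1475 higher and 1686 lower, or 1794 and 1689 with median-ratio scaling, and 19 of 21 alternative activation genes rose (19 adjusted over the list alone, camera adjusted p = 0.000112 with an estimated correlation). Integrated stress response genes (12 of 16 up, 14 adjusted over the list alone), cell cycle genes (11 of 26 up, 14 adjusted over the list alone) and alveolar macrophage identity genes (11 up and 5 down of 21, 11 and 6 adjusted over the list alone) had camera adjusted p = 0.00387, 0.0477 and 0.0477 with an estimated correlation. Epithelial markers were lower (2 of 5 down, 3 adjusted over the list alone, camera adjusted p = 0.0477 with an estimated correlation), with Hopx at -0.60 and Epcam at -0.65. Tnf fell (log2 -0.68, limma adjusted p = 4.58e-06), whereas Il1b (2.08) and Il1a (0.86) rose. Over the 3932 genes called for IL-13 against untreated, 96.2% had the same sign here and 65.2% were called again in these separate libraries.

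The central comparison asked what IL-33 added to IL-13. Cxcl3 fell from 147 ± 11.9 TPM with IL-13 to 26.5 ± 1.39 TPM with IL-33+IL-13 (log2 -2.43, limma adjusted p = 8.62e-07). Pf4, which encodes platelet factor 4, fell from 37.3 ± 3.8 to 13.4 ± 6.41 TPM (-1.50, adjusted p = 0.0224). Eef1a2, an elongation factor gene, fell from 9.04 ± 0.469 to 2.82 ± 0.23 TPM (-1.40), and Gsta2, a glutathione transferase gene with close paralogs and so uncertain, from 5.40 ± 0.487 to 1.58 ± 0.42 TPM (-1.32). Acod1, which makes itaconate, fell from 24.7 ± 2.89 to 9.47 ± 1.99 TPM (-1.30). Aebp1 rose from 12.4 ± 0.313 to 26.3 ± 3.15 TPM (1.02, adjusted p = 9.07e-07), and the steroid enzyme gene Hsd17b1 from 7.28 ± 0.849 to 14.8 ± 2.26 TPM (0.93). The phospholipase-like gene Plbd1 rose from 3.01 ± 0.0772 to 6.01 ± 0.587 TPM (0.80), the retinol carrier gene Rbp4 from 31.05 ± 2.87 to 48.9 ± 4.71 TPM (0.64) and Lyl1 from 6.38 ± 0.247 to 10.1 ± 1.78 TPM (0.58).

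Of 26 cell cycle genes 13 fell with IL-33+IL-13 against IL-13 and none rose (20 adjusted over the list alone, camera adjusted p = 1.55e-25, and adjusted p = 0.000461 with an estimated correlation). Mki67 went from 6.53 ± 0.32 to 2.33 ± 0.36 TPM, Top2a from 3.88 ± 0.10 to 1.55 ± 0.22 TPM and Mcm7 from 39.0 ± 0.81 to 24.7 ± 1.7 TPM. Of 21 NF-kB targets 4 fell (1 up and 8 down adjusted over the list alone, camera adjusted p = 3.74e-06, but adjusted p = 0.172 with an estimated correlation), among them Il1b, from 66.01 ± 6.4 to 33.4 ± 2.8 TPM, and Cxcl2, from 76.5 ± 6.4 to 40.4 ± 8.5 TPM. Of 18 hypoxia and glycolysis genes 5 fell (9 adjusted over the list alone, camera adjusted p = 7.47e-06, but adjusted p = 0.172 with an estimated correlation). Of 21 cholesterol synthesis genes 2 fell (6 adjusted over the list alone, camera adjusted p = 7.47e-06, but adjusted p = 0.284 with an estimated correlation). Of 21 alternative activation genes 3 fell and 1 rose (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.00403, but adjusted p = 0.23 with an estimated correlation): Chil3 went from 5170 ± 130 to 4340 ± 170 TPM, and Retnla, at 0.311 ± 0.54 and 2.37 ± 1.4 TPM, was the one higher. Mmp19 fell from 473 ± 7.6 to 284 ± 15 TPM and Igf1 from 20.7 ± 1.4 to 14.1 ± 0.73 TPM, and Spp1 rose from 352 ± 17 to 479 ± 13 TPM. Antigen presentation genes were called higher by camera (adjusted p = 0.0466), but with adjusted p = 0.172 with an estimated correlation and no member called. limma called 340 genes, 110 higher and 230 lower, of which 4 and 20 changed by at least 2-fold. The count was 212 without IL-13 replicate 1, 212 without IL-13 replicate 3 and 217 without IL-33+IL-13 replicate 3. It was 148 with only the 2 groups in the fit and 764 with a covariate for each library's slope on transcript length. Of the 284 genes also called for IL-13 against untreated, which shares the IL-13 libraries, 255 moved against the direction of IL-13. Because the IL-13 libraries enter both with opposite sign, chance alone favours opposite directions in this count.

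**Figure D3:**
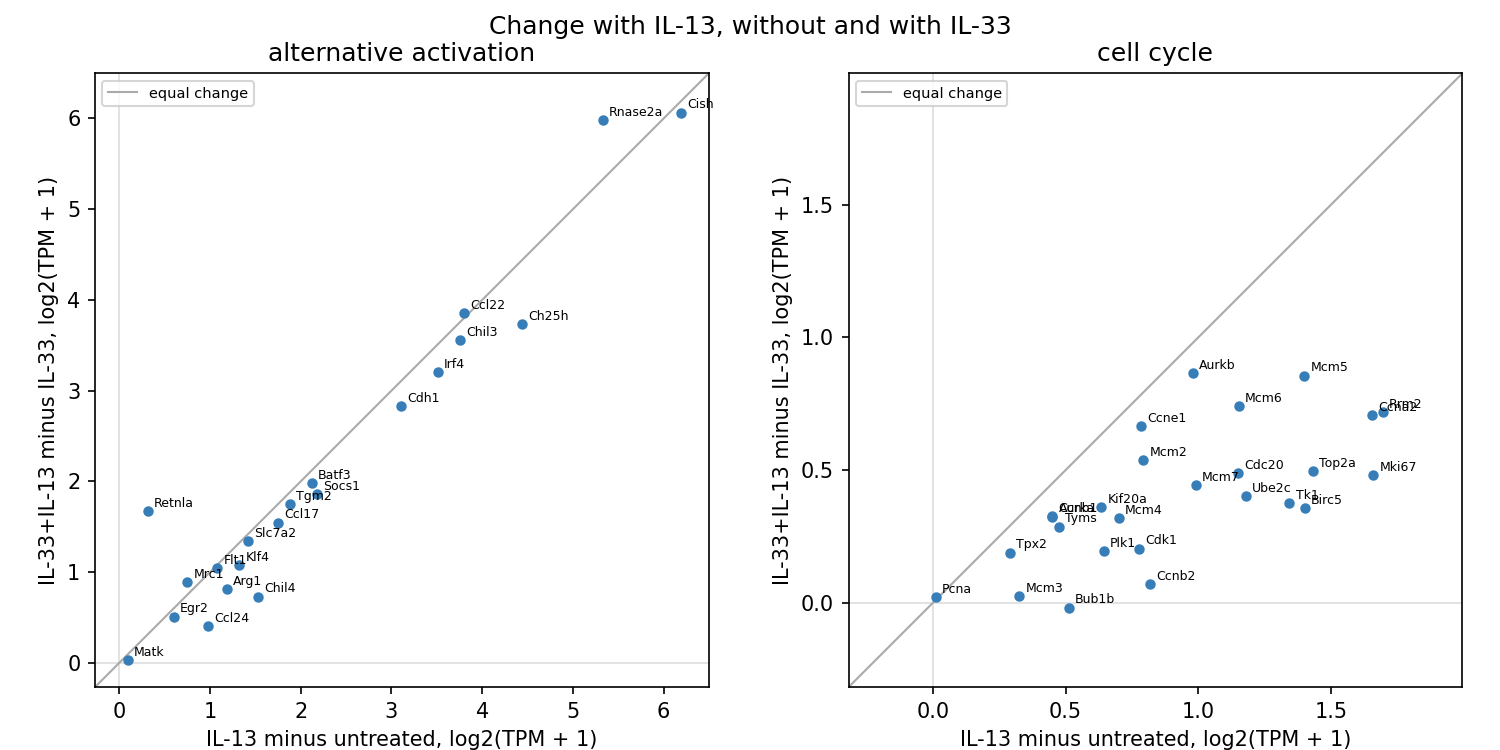
Change with IL-13 in log2(TPM + 1) without IL-33 (x axes, IL-13 minus untreated) and with IL-33 (y axes, IL-33+IL-13 minus IL-33), 1 point per tested gene of the list named above each panel, with the line of equal change. Among genes of alternative activation Cish lies near the line, at 6.20 and 6.06, while Ch25h (4.44 and 3.73) and Chil4 lie below it and Retnla above, and Mki67 of the cell cycle genes is at 1.66 without IL-33.

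Whether IL-33 changed the answer to IL-13 was tested by their interaction in the absence of IL-17A. Cxcl3 had the largest negative term (log2 -2.57, limma adjusted p = 5.61e-05), followed by Eef1a2 (-1.69), H2-M2, a class I-like histocompatibility gene (-1.68), Acod1 (-1.51) and Gsta2 (-1.48). The largest positive terms were Hsd17b1 (0.965), Gchfr, a regulator of tetrahydrobiopterin synthesis (0.93), Plbd1 (0.86), Apoe (0.80) and Aebp1 (0.79). H2-M2 went from 0.753 ± 0.398 TPM in untreated cells to 8.92 ± 1.35 with IL-13, and from 1.39 ± 0.137 with IL-33 to 3.32 ± 0.776 with both. limma called 155 genes, 52 with a positive and 103 with a negative term. Cell cycle genes were lower as a group (4 of 26 negative, 15 adjusted over the list alone, camera adjusted p = 1.37e-16, and adjusted p = 0.00446 with an estimated correlation), with Mki67 at -1.18 (adjusted p = 0.0089). NF-kB targets had 4 of 21 negative terms (8 adjusted over the list alone, camera adjusted p = 5.44e-09, but adjusted p = 0.0724 with an estimated correlation), namely Cxcl3, Il1b (-1.32), Tnf (-0.63) and Sod2 (-0.34). Other lists were lower by camera but not with an estimated correlation. Hypoxia and glycolysis (1 negative, 8 adjusted over the list alone, camera adjusted p = 6.54e-07), cholesterol synthesis (0 called, 1 adjusted over the list alone, adjusted p = 9.3e-05), alternative activation (2 negative, 1 positive and 3 negative adjusted over the list alone, adjusted p = 0.00219) and matrix genes (1 positive and 3 negative, 2 and 6 adjusted over the list alone, adjusted p = 0.0106) had adjusted p = 0.11, 0.303, 0.239 and 0.239 with an estimated correlation. The count of genes was 95 without the 4 libraries numbered above 24 and 427 with the covariate for transcript length.

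With all 3 cytokines Cish was at 133.5 ± 7.15 TPM, Cxcl3 at 23.1 ± 1.42 TPM, Chil3 at 4080 ± 114 TPM and Mki67 at 1.89 ± 0.772 TPM. Against untreated cells the largest log2 increases were Cish (6.19), Rnase2a (5.14), Ocstamp (4.55), Ch25h (3.97), Ccl22 (3.42), Chil3 (3.42), Mmp13 (3.25) and Irf4 (3.23). The largest decreases were Lrrc14b (-2.70), Hp (-2.64), Cdo1 (-2.07), Lyl1 (-2.01), Cxcl16 (-1.85), Sema4d (-1.81), Ndrg1 (-1.81) and Pilrb2 (-1.80). Alternative activation (19 of 21 up), the integrated stress response (14 of 16 up) and alveolar macrophage identity (10 up and 5 down of 21) had camera adjusted p = 8.28e-05, 0.00168 and 0.0456 with an estimated correlation. Adjusted over the list alone these counts were 20, 14, and 10 up with 5 down. limma called 3710 genes, 1367 higher and 2343 lower, and with median-ratio scaling 1966 higher and 1837 lower, so the balance of directions rested on the scaling. With only these 2 groups in the fit the count was 1554, and the highest count in another split of the same 6 libraries was 1301.

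Adding IL-17A to IL-33+IL-13 gave Tnf at 139 ± 7.25 TPM beside 99.6 ± 6.14 TPM (log2 0.48, limma adjusted p = 0.126), the smallest adjusted p of the NF-kB list, and Cxcl2 at 54.0 ± 5.19 beside 40.4 ± 8.48 TPM. limma called 0 genes (826 at an unadjusted p under 0.05, smallest adjusted p 0.13), as did voom on recovered reads, and camera called no list (1 NF-kB target higher and 1 monocyte gene lower adjusted over the list alone). Adding IL-17A to IL-33 gave Tnf at 121 ± 10.7 beside 160.1 ± 17 TPM (-0.40, adjusted p = 0.535) and Il1b at 4.45 ± 0.285 beside 7.15 ± 1.12 TPM (-0.57, adjusted p = 0.535). limma called 0 genes there (497 at an unadjusted p under 0.05, smallest adjusted p 0.54), as did voom on recovered reads. The NF-kB list was lower by camera (2 down adjusted over the list alone, adjusted p = 1.33e-09, but adjusted p = 0.105 with an estimated correlation). The interaction of IL-33 and IL-17A gave 0 genes by limma (466 at an unadjusted p under 0.05, smallest adjusted p 0.39), with Tnf at -0.40 and Il1b at -0.58. Its NF-kB term was negative by camera (2 down adjusted over the list alone, adjusted p = 5.04e-05, but adjusted p = 0.446 with an estimated correlation). Lipid handling (positive, adjusted p = 0.0344) and the integrated stress response (negative, adjusted p = 0.0464) had adjusted p = 0.658 and 0.45 with an estimated correlation. Averaged over the 4 backgrounds, IL-17A gave 0 genes by limma (440 at an unadjusted p under 0.05, smallest adjusted p 0.78), and the 95% interval excluded a 2-fold change for 99.7% of genes at 10 TPM or more.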

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

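The tests of explanations in this part, including the splits of libraries and the comparisons of IL-33 with IL-17A present, were chosen or written down only after the result was seen.

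The effect of IL-33 differed between cells with and without IL-13, by a test of the difference itself. The interaction of IL-33 and IL-13 gave 155 genes in cells without IL-17A and 200 in the separate libraries with IL-17A (limma), 83 positive and 117 negative in the second. The 200 moved more with the processing. Without libraries numbered above 24, IL-33+IL-17A held 1 library, so the count for that setting is not weighed here. With only the groups compared in the fit the count was 70. It was 132 and 105 without IL-17A replicates 1 and 2, 125, 124 and 124 without IL-13+IL-17A replicates 1, 2 and 3, and 122 and 129 without IL-33+IL-17A replicates 2 and 3. The 155 was 95 without libraries numbered above 24 and 427 with a covariate for transcript length. Cxcl3 had interaction terms of -2.57 and -2.76, Acod1 of -1.51 and -1.61, Mki67 of -1.18 and -1.68, and Aebp1 of 0.79 and 0.89. Tnf, at -0.63 in the first test, changed little with IL-33 in the second set. It was at 140 ± 9 TPM with IL-13+IL-17A and 139 ± 7.3 in the triple combination. With IL-17A it was at 127 ± 7.3 TPM and with IL-33+IL-17A at 121 ± 11. Of the 155 genes, 149 had the same sign with IL-17A present and 93 were called there again. Cell cycle genes were lower in the second test as well (13 of 26 negative, 21 adjusted over the list alone, camera adjusted p = 6.58e-19, and adjusted p = 0.00232 with an estimated correlation). Among 100 splits that reassigned a cytokine within each background, 2 gave as many genes in each test, the real one and 1 other. Those others gave 156 and 209, each from a split that kept the groups with IL-13 as they were.

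IL-33 itself, set against IL-13 with IL-17A in both groups, gave 469 genes, 152 higher and 317 lower, or 255 higher and 327 lower with median-ratio scaling. The count was 294, 308 and 287 without replicates 1, 2 and 3 of IL-13+IL-17A and 311 without replicate 2 of the triple combination. It was 60 with only the 2 groups in the fit, 763 with the covariate for transcript length and 745 with voom and a filter on reads. Of the 340 genes called for IL-33+IL-13 against IL-13, 335 had the same sign in this second set. Both comparisons called 246 genes, where 12.1 would be in both if the 2 lists were independent. They share 1 fit and its estimate of each gene's spread, so the lists are not fully independent and 12.1 may be too low. Averaged over both backgrounds with IL-13, IL-33 gave 926 genes, 334 higher and 592 lower, or 519 and 588 with median-ratio scaling, and of 100 splits only the real one (1 of 100) gave as many, with 7 genes as the highest other.

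A library batch shared by every group with IL-33 was argued against as the source of this pattern. On the 469 genes of the second set the median shift in the direction seen there was 0.259 for IL-33+IL-13 against IL-13, but -0.031 for IL-33 against untreated (range leaving 1 library out -0.04 to -0.01). A batch of the groups with both cytokines cannot be told apart from their joint effect: on the 340 genes of the first set the triple library numbered outside the run shifted by 0.275, like the other 2 (0.286 and 0.32), but a single library cannot exclude such a batch. A weaker action of IL-13 beside IL-33 was argued against for the 8 of 16 genes called in opposite directions that were so called again in the separate libraries with IL-17A, and one alike for all genes by the ratio of its effects with and without IL-33, 0.441 (0.411 to 0.468 leaving 1 library out) for cell cycle and 0.948 (0.925 to 0.974) for alternative activation genes. A weakening that differs between genes, with a ratio of 0.792 over 365 genes chosen in other libraries, and an answer by other cells, since Il1rl1, the IL-33 receptor gene, had 57 estimated reads in all, stay open.

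For the absence of genes past the threshold with IL-33 or IL-17A alone, missed changes of 2-fold were argued against for most genes at 10 TPM or more, where 98.1% and 98.0% of intervals excluded them. They stay open below 10 TPM, where 73.6% and 73.8% did on the log2(TPM + 1) scale, which understates the change of low genes. With IL-13, where 3932 genes were called, the share at 10 TPM or more was 94.1%. A high share therefore does not show that few genes responded. Too little power for smaller changes stays open at every level for most genes, since 62.5% of the smallest simulated changes were recovered at 10 TPM or more. For IL-33, missed small shifts are argued against only for 469 genes as a set and only in 1 direction. These genes were called for the triple combination against IL-13+IL-17A, and the direction is the one seen there. Their median shift in that direction was 0.259 in log2 with IL-33 beside IL-13. It was -0.031 with IL-33 alone (-0.04 to -0.01 leaving 1 library out) and -0.016 with IL-33 added to IL-17A (-0.027 to -0.001). Of the 469 genes, 32% and 40.3% moved in that direction in these 2 comparisons. Small shifts in the other direction or in mixed directions therefore stay open. Few transcripts of the receptor subunit gene Il17rc, at most 0.724 TPM as a group mean, could leave IL-17A without effect, but no group with more Il17rc was there to test it.

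With 3 libraries in each group the 10 splits of a pair of groups are too few for a share under 0.05. The real grouping gave the highest count (1 of 10) for IL-13 (highest other 1), IL-33+IL-13 (2), IL-13+IL-17A (1) and the triple combination (1301) against untreated, for IL-33+IL-13 against IL-13 (1) and against IL-33 (1), and for the triple combination against IL-13+IL-17A (0). Where limma called no gene the splits say nothing, since every split gives at least 0: the counts were 10 of 10 for pairs of groups. They were 100 of 100 for the interactions of IL-17A with IL-33 and with IL-13, for IL-17A averaged over 4 backgrounds and for IL-33 averaged over the 2 without IL-13, with 0 or 1 as the highest other.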

How the results depend on the processing

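The tests without the libraries that stand apart, with voom, with median-ratio scaling, with a covariate for transcript length, of IL-33 or its interaction with IL-17A present, and averaged over backgrounds were chosen only after results were seen. edgeR, with its RLE factors, and DESeq2 were not run on the TPM values used here. Median-ratio scaling of TPM and voom on recovered reads were run instead. Of 150 counts of genes for the 15 comparisons planned, 139 stayed within 1.5 times and 11 moved, and 9 counts of the added comparisons moved as well. A count of 0 that stayed at 0 was among the 139, so comparisons without a called gene add to that number. The values followed were 441, of 124 named genes, all called in the main fit. The settings reuse libraries of that fit, so a reversal was unlikely beforehand. None of 4382 such values turned its direction under these settings, while 124 lost the threshold. With single libraries left out, none of 2805 values turned and 185 lost the threshold, with fewer libraries in each fit. Camera kept 18 of 61 called lists with an estimated correlation and 280 of 305 calls under other settings. The cause was not tested for any of the moves that follow, except that fewer libraries enter where some are left out or only the groups compared are fitted.

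With only the groups compared in the fit limma called 2 genes for IL-33, 5 for IL-17A, 3 for IL-33+IL-17A and 1554 for the triple combination, each against untreated. It called 148 for IL-33+IL-13 against IL-13, 6 for IL-33+IL-17A against IL-33, 60 for the triple combination against IL-13+IL-17A and 70 for the interaction of IL-33 and IL-13 with IL-17A present. Without libraries numbered above 24 it called 1 gene for IL-33+IL-17A against IL-33, 1 for the interaction of IL-33 and IL-17A (Gm47155 in each), 95 for that of IL-33 and IL-13 and 55 for the same with IL-17A present. In that setting IL-33+IL-17A held replicate 1 only. All of these counts but the 95 use that group, so they rest on 1 library there. They cannot show whether the comparisons depend on the libraries left out. With the covariate for transcript length limma called 764 genes for IL-33+IL-13 against IL-13, 427 for the interaction of IL-33 and IL-13 and 763 for the triple combination against IL-13+IL-17A. It called 1672 for IL-33 averaged over backgrounds with IL-13 and 3 for those without (Pcyox1, Man2a2 and Brms1). With no filter on low values 1 gene, Brms1, was called for IL-33 averaged without IL-13. With voom and a filter on reads 745 were called for the triple combination against IL-13+IL-17A. Without the libraries that stand apart 115 were called for the interaction with IL-17A present.

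With single libraries left out the ranges were 212 to 261 for IL-33+IL-13 against IL-13, 287 to 667 for the triple combination against IL-13+IL-17A, 105 to 237 for the interaction of IL-33 and IL-13 with IL-17A present, and 0 to 1 for the interaction of IL-33 and IL-17A, for IL-17A averaged over 4 backgrounds and for IL-33 averaged without IL-13. In the interaction with IL-17A present the count was 132 and 105 without IL-17A replicates 1 and 2, 125, 124 and 124 without IL-13+IL-17A replicates 1, 2 and 3, and 122 and 129 without IL-33+IL-17A replicates 2 and 3. The single calls came without IL-17A replicate 1 (interaction of IL-33 and IL-17A, IL-33 averaged) and without IL-13 replicate 2 (IL-17A averaged). Genes below 10 TPM had the wider intervals, with a median half-width of the 95% interval of 0.32 in log2 beside 0.16 for the others.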

Other observations

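The 2 gene lists, the genes of opposite direction and the tests of transcript length in this part were chosen only after the result was seen.

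Several genes of antioxidant defence and NADPH supply, among them known targets of the transcription factor Nrf2, rose with IL-13 and fell when IL-33 was added to it. Nqo1, a quinone reductase gene, was at 2.5 TPM in untreated cells, 8.3 ± 0.61 TPM with IL-13 and 2.99 ± 0.063 TPM with IL-33+IL-13 (SD, n = 3). Gclm, a subunit of the first enzyme of glutathione synthesis, was at 31.3, 63.3 ± 2.2 and 39.8 ± 0.82 TPM, and Srxn1, sulfiredoxin, at 685, 1010 ± 19 and 647 ± 28 TPM. Of 29 tested genes 22 rose and 3 fell with IL-13, and 18 fell and none rose with IL-33+IL-13 against IL-13 (median log2 -0.328). In the separate libraries with IL-17A 22 fell (median -0.341, camera p = 3.96e-08 with an estimated correlation). With IL-33 and no IL-13 the list leaned the other way: 20 of 29 were positive against untreated (median 0.047, camera p = 0.00696 with an estimated correlation) and 21 when averaged over 2 backgrounds (median 0.053, p = 0.000462), with no gene called by limma. Lysosomal genes went the other way: Hexa, a hexosaminidase gene, was at 477, 346 ± 1.4 and 396 ± 5.3 TPM, and the cathepsin gene Ctsd at 8710, 6280 ± 140 and 7120 ± 130 TPM. Of 35 such genes 32 fell with IL-13, and 13 rose with IL-33 in each set, with camera p = 0.00162 with an estimated correlation in the second. With IL-33 and no IL-13, 33 of the 35 were negative against untreated (median -0.034, camera p = 0.0728 with an estimated correlation), and 19 when averaged over 2 backgrounds (p = 0.711). Both lists were put together from genes seen to move with IL-33+IL-13, so these p do not show that either class as a whole moved.

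Some genes were called for IL-13 in opposite directions without and with IL-33, 16 of the 2565 called in both. With IL-17A present there were 17 of 2747, and 8 were shared (Alas1, Ass1, Cat, Clec4n, Prdx1, Prdx6, Srxn1 and Taldo1). Srxn1 rose by 0.56 with IL-13 alone and fell by 0.22 with IL-33+IL-13 against IL-33, Prdx1, a peroxiredoxin gene, rose by 0.34 and fell by 0.28, and Clec4n, which encodes dectin-2, rose by 0.26 and fell by 0.59. When IL-17A took the place of IL-33, 1 of 3191 genes called in both went in opposite directions.

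On the second principal component untreated replicate 1, IL-17A replicate 2 and replicate 2 of the triple combination stood apart. Over 6811 genes the loading followed log2 transcript length with r = -0.605, so an excess of shorter transcripts in these libraries fits the pattern. Replicate 2 of the triple combination had a slope on length of -0.228, beside -0.086 to 0.098 in all others. No biological explanation was tested, since the design sets none of these libraries apart.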
